A study of Homo sapiens with 16 samples.

How the data were processed

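RNA was sequenced from 16 libraries of human lung adenocarcinoma cells: the established line A549 and its cisplatin-resistant derivative A549/cDDP. Per the labels' protocols, 35000 cells were seeded per well, cisplatin was used at a labelled 15 mM for 24 h against its solvent, and A549/cDDP was kept in medium with the same labelled concentration of cisplatin between experiments. The unit of that concentration is printed as the labels give it and was not checked here. Transfected cells received 12 pmol of a gapmer, an antisense oligonucleotide that directs RNase H to its target RNA, and were collected 48 h after transfection, the last 24 h in drug or solvent. The mRNA was enriched with oligo(dT) beads, per the labels' protocols.

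The deposited values are FPKM (fragments scaled by gene length and by the library total), 1 column per library and 60448 gene identifiers. The authors aligned reads with TopHat2 and counted them with HTSeq 0.6.1 on build hg38, per the submitters' processing notes. The annotation release and the strand setting of the counting are not stated. No scaling beyond the library total was detected or stated for the deposited FPKM. Gene symbols, positions (hg38) and exon lengths came from GENCODE release 29, which held a model for 56868 of the identifiers.

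The depth behind the FPKM was recovered from low values, which are whole multiples of the value of 1 read. It came to between 31350000 and 43140000 fragments per library. With GENCODE exon lengths, 60.2% of the 22675 genes with at least 2 low values had whole read numbers in these libraries at a tolerance of 0.02 reads, so read numbers for single genes are approximate. A gene at 0 in a whole group was set against the level that 3 reads over the group would give. Such floors cover counting error only, since PCR copies of 1 molecule are not independent.

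Genes with a mean of at least 0.5 FPKM over the 16 libraries were tested, 17198 in all. Values were placed on the scale log2(FPKM + 0.5), and every log2 change below is on it. One limma model (version 3.58.1, R 4.3.3) with 1 mean per group for 8 groups of 2 libraries and a trended prior on the spread gave each comparison, two-sided, with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. Sharing 1 fit leaves 8 residual degrees of freedom. The words rose, fell, higher and lower are used for genes past that threshold. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between libraries. A test of the fit on simulated data with the real means, run on 16944 genes, recovered 78.8% of genes changed by 0.5 on the log2 scale and 94% of those changed by 1 for cisplatin in A549, with 5.8% of calls false. For the SCAT7 gapmer in solvent the same test recovered 75.8% and 97%, with 5.2% of calls false. The simulation changed a small part of the genes in 1 group and gave all groups the same spread. In the data the median absolute log2 difference between replicates was 0.066 for A549 in solvent. It was 0.122 for the SCAT7 gapmer in cisplatin, and far more genes were called. These shares of false calls therefore hold for the simulated setting only.

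Lists of genes (26 in all) were fixed before the data were examined, together with the tests, the comparisons and the rule for naming genes. They cover damage-induced genes (CDKN1A, MDM2 and others that cells raise after DNA damage), mitosis, S phase, Fanconi anaemia and homologous recombination, nucleotide excision repair, damage signalling, topoisomerase 1 and its repair, apoptosis regulators, platinum transport, metallothioneins, NRF2 targets, ATF4 and ER stress, interferon response, NF-kB and cytokines, immediate early genes, epithelial genes, mesenchymal genes, YAP targets, cholesterol synthesis, hypoxia and glycolysis, FGF receptors and cyclin D, lung epithelium markers, other-lineage markers, the deleted locus on chromosome 9, mitochondrial transcripts and polyadenylated histone genes. Each list was tested with camera on the same fit, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The count of members past the threshold is given over all genes tested, and "adjusted over the list alone" where that count differs.

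The genes named were ELF3-AS1, ELF3, CDKN1A, MDM2, TOP1, HNRNPK and YBX1, then in each comparison up to 8 genes with the largest rise and 8 with the largest fall among called genes with a mean of at least 5 FPKM in the higher group and no overlap between both groups' libraries (5 and 5 for a difference of effects, without the last condition), and up to 4 members of each called list. Pseudogenes, repeated symbols and sex-linked marker genes were left out of the largest changes, and a few genes that this rule names are not reported here. Calls of 2 comparisons were set against each other with Fisher's exact test, two-sided, where they share no library; overlaps with cisplatin in A549, other than that of cisplatin in A549/cDDP, were chosen after the results were seen. Correlations of log2 changes are across genes, which are not independent replicates. Fisher's exact test takes genes as independent too, so its p-values do not allow for genes that change together.

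Alternatives covered the pseudocount, the filter, median ratio scaling, quantile normalization, a fit of only the libraries compared, stricter thresholds, a replicate block and leaving out each library in turn. A further 3 were added after the data were seen: voom on approximate reads, a fit of the untransfected or the transfected libraries alone, and a fit without the SCAT7 gapmer libraries. Tables were prepared with python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots with matplotlib 3.10.9.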

Results

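The libraries fall into 8 groups of 2. A549 and A549/cDDP were each measured in solvent and in cisplatin without transfection. A549/cDDP was also transfected with a control gapmer or with a gapmer against the long noncoding RNA SCAT7, each in solvent and in cisplatin. Depth ran from 31350000 to 43140000 fragments per library, with the 4 SCAT7 gapmer libraries at 31350000 to 33400000 and the 4 control gapmer libraries at 42300000 to 43140000. Replicates correlated across genes at 0.991 to 0.996 on the log2 scale. The first principal component held 52.4% of the variance, the next 18.5%. Values below are means ± SD in FPKM (n = 2 libraries per group).

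SCAT7 was taken as the RNA of the antisense gene ELF3-AS1 (ENSG00000234678), for which the RefSeq gene table gives SCAT7 as another name; the labels name SCAT7 only. The gene overlaps the start of ELF3, the gene of an epithelial transcription factor, on the opposite strand. Its level asks first whether the knockdown can be seen. In solvent, ELF3-AS1 stood at 3.06 ± 0.716 FPKM with the control gapmer and 0.716 ± 0.171 with the SCAT7 gapmer, and it fell by 1.54 on the log2 scale (limma adjusted p = 7.5e-06). In cisplatin it stood at 3.48 ± 0.351 and 1.93 ± 0.346, and fell by 0.71 (limma adjusted p = 0.00355). About 104 and 156 reads lie behind ELF3-AS1 in the SCAT7 gapmer libraries in solvent. ELF3-AS1 spans chromosome 1, 201995696 to 202010463 on hg38, and ELF3 (ENSG00000163435) spans 202007945 to 202017188. The genes share 2519 bp on opposite strands, and the strand setting of the counting is not known, so reads of ELF3 in that stretch cannot be told from reads of ELF3-AS1. ELF3 itself rose with the SCAT7 gapmer, from 37.1 ± 0.641 to 49.5 ± 0.93 FPKM in solvent (log2 change 0.41, limma adjusted p = 7.09e-05).

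Cisplatin crosslinks DNA, and cells answer with damage-induced genes that stop the cycle, start repair or prepare apoptosis. In the parental line A549, cisplatin raised all 29 damage-induced genes and lowered all 25 mitosis genes. CDKN1A, the cyclin-dependent kinase inhibitor p21, and MDM2, a ubiquitin ligase gene, were among the strongest responders. The replication genes MCM2, MCM5 and MCM6 and the crosslink repair genes BRCA1, FANCI and FANCA fell with the mitosis genes, and inflammatory genes such as CXCL8 and TNFAIP3 rose. SCAT7 and its neighbour ELF3 rose too.

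CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) went from 84.2 ± 0.123 to 1620 ± 17.7 FPKM in A549 (log2 change 4.26, limma adjusted p = 7.77e-17). MDM2 (ENSG00000135679, chromosome 12, 68808176 to 68850686) went from 57.7 ± 1.25 to 811 ± 10.6 (log2 change 3.80, limma adjusted p = 6.09e-13). ELF3-AS1 rose from 3.12 ± 0.211 to 14.2 ± 1.36 (log2 change 2.02, limma adjusted p = 3.78e-07). ELF3 rose from 57.2 ± 3.43 to 99.9 ± 1.9. TOP1 (ENSG00000198900, chromosome 20, 41028818 to 41124487), the topoisomerase 1 gene, rose by 0.20 on the log2 scale. HNRNPK (ENSG00000165119, chromosome 9, 83968083 to 83980616), an RNA-binding protein gene, fell by 0.29. YBX1 (ENSG00000065978, chromosome 1, 42682427 to 42702349), which encodes another RNA-binding protein, fell by 0.11, a call that ends under quantile normalization (-0.07, limma adjusted p = 0.139).

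In all, 10393 of 17198 genes passed in A549, 5729 higher and 4664 lower, and 1258 and 857 of them changed at least 2-fold. The majority turned with scaling, to 5062 higher and 5328 lower with median ratio scaling and 4762 and 5224 with quantile normalization. The largest rises were in SLC52A1, a riboflavin transporter (0.341 ± 0.00972 to 61.6 ± 2.23 FPKM), the adhesion genes NECTIN4 and CEACAM1, the glutamate receptor subunit GRIN2C, HES2, PLXNB3 and CD82. LCE1F, a cornified envelope gene, was at 0 in both solvent libraries and at 14.8 ± 0.891 in cisplatin, at least 127-fold higher against 3 reads over the group. The largest falls were in SLIT3, the helicase gene PIF1 (28.3 ± 0.249 to 1.83 ± 0.226 FPKM), the cytokine IL11, the exocyst gene EXOC4, PLK1, CDH4, SPOCK1 and NTRK3.

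The damage-induced genes had a median log2 change of 2.49 (camera adjusted p = 7.7e-22, and 0.00282 with an estimated correlation). The Fanconi anaemia and homologous recombination genes, 21 of 26 lower and 1 higher, had a median of -1.40 (camera adjusted p = 1.41e-10, and 0.0206 with an estimated correlation). For mitosis genes (25 of 25 lower, median -2.19) the camera adjusted p was 1.91e-17, and 0.167 with an estimated correlation. For S phase genes (23 of 25 lower, 1 higher) it was 3.14e-16, and 0.0818 with an estimated correlation. NF-kB and cytokine genes were higher for 18 of 20 and lower for 1 (camera adjusted p = 1.44e-06, and 0.235 with an estimated correlation). Apoptosis regulators, APAF1, BAK1 and BIK among them, were higher for 14 of 22, 15 adjusted over the list alone, and lower for 2 (camera adjusted p = 0.00217, and 0.167 with an estimated correlation). NRF2 targets were lower for 19 of 25 and higher for 4, ALDH3A1 and CYP4F11 among the latter (camera adjusted p = 0.000475, and 0.433 with an estimated correlation). Damage signalling genes such as H2AX and CHEK1 were lower for 14 of 23 and higher for 5 (camera adjusted p = 0.000995, and 0.0692 with an estimated correlation).

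Genes of the mesenchymal list such as FN1 and CDH2 were lower for 15 of 21 in A549, 16 adjusted over the list alone, and higher for 3, ACTA2 being the strongest (camera adjusted p = 0.00115, and 0.156 with an estimated correlation). Cholesterol synthesis genes were lower for 11 of 20 and higher for 3 (camera adjusted p = 0.00568, and 0.129 with an estimated correlation). FGF receptors and cyclin D, a list tied to earlier work on SCAT7, were lower for 8 of 14 and higher for 2, with FGFR1, FGFR4 and CDK4 among the falls (camera adjusted p = 0.014, and 0.167 with an estimated correlation). Immediate early genes were lower for 10 of 15 and higher for 3, 5 adjusted over the list alone (camera adjusted p = 0.0319, and 0.433 with an estimated correlation or 0.0536 after quantile normalization), while ATF3 in that list rose from 3.04 ± 0.0229 to 40.2 ± 1.21 FPKM.

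**Figure D1:**
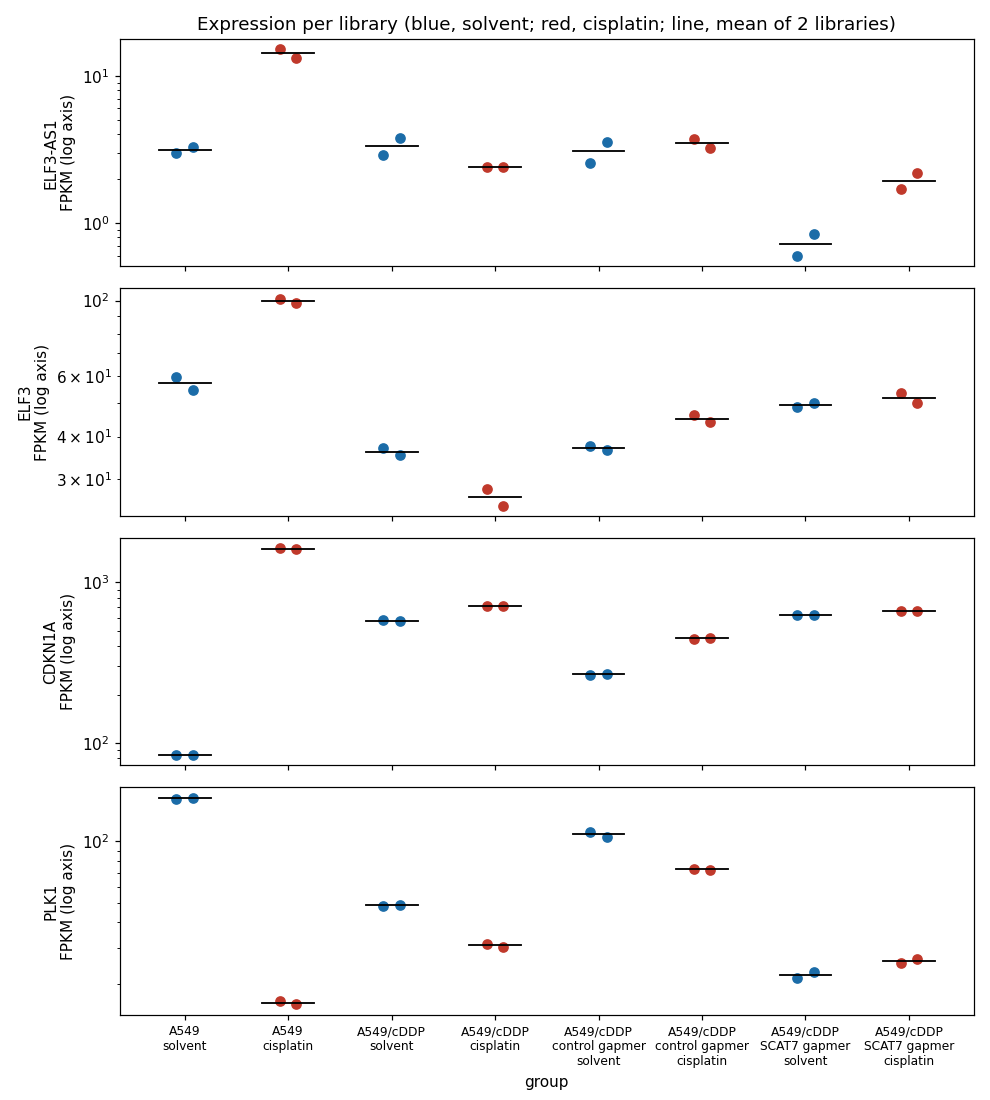
FPKM (log axis) of each library for the genes on the vertical axes, by group on the horizontal axis. Points are libraries, blue in solvent and red in cisplatin, and lines are means of 2 libraries. CDKN1A goes from 84.2 to 1620 FPKM with cisplatin in A549 and from 577 to 709 in A549/cDDP, and ELF3-AS1 is lowest, at 0.716 FPKM, with the SCAT7 gapmer in solvent.

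In the resistant line A549/cDDP the question was which part of the drug response remains. Mitosis genes such as PLK1 and CENPF and repair genes such as BRCA1 and FANCA fell here too, by less than in A549, while the damage-induced genes moved little. CDKN1A rose slightly and MDM2 did not pass. Immediate early genes, which growth factors and stress induce within an hour, went up, with FOS and EGR1 first. SCAT7 did not pass and its mean was lower in cisplatin.

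Cisplatin changed 1393 genes in A549/cDDP, 611 higher and 782 lower, of which 12 and 5 changed at least 2-fold. A fit of only the libraries compared left 417. CDKN1A went from 577 ± 4.79 to 709 ± 1.64 FPKM (log2 change 0.30, limma adjusted p = 0.000133). MDM2 stood at 291 ± 0.833 and 306 ± 10.1 (limma adjusted p = 0.572). ELF3-AS1 stood at 3.34 ± 0.635 and 2.41 ± 0.00294 (limma adjusted p = 0.192), and ELF3 fell from 36.1 ± 1.3 to 26.6 ± 2.03. TOP1, HNRNPK and YBX1 did not pass (limma adjusted p = 0.086, 0.447 and 0.231); after quantile normalization TOP1 did, with a log2 change of -0.15. FOS, a transcription factor of the immediate early response, rose from 0.642 ± 0.0694 to 7.11 ± 2.19 FPKM. The other large rises included LINC01629, SHC2 and IGF2. The largest falls were in LCN2, an iron-binding secreted protein, AGFG2, PKDCC, CNTN1, DHRS3, FRAS1, IMMP2L and ATOH8.

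Mitosis genes fell for 25 of 25 in A549/cDDP with a median of -0.56 (camera adjusted p = 5.58e-30, and 0.0594 with an estimated correlation). Of 29 damage-induced genes 10 were higher, 17 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 4.65e-12, and 0.0123 with an estimated correlation). The S phase genes were lower for 18 of 25, 21 adjusted over the list alone (camera adjusted p = 9.97e-19, and 0.0443 with an estimated correlation). The Fanconi anaemia and homologous recombination genes were lower for 16 of 26, 19 adjusted over the list alone (camera adjusted p = 5.17e-14, and 0.0123 with an estimated correlation). Immediate early genes were higher for 9 of 15, 10 adjusted over the list alone (camera adjusted p = 2.14e-11, and 0.0443 with an estimated correlation). Mesenchymal genes such as MMP2 and FSTL1 were higher for 6 of 21, 13 adjusted over the list alone, and lower for 1, FN1 (camera adjusted p = 2.81e-06, and 0.0443 with an estimated correlation). ATF4 and ER stress genes, TRIB3 and CHAC1 among them, were higher for 9 of 20, 10 adjusted over the list alone, and lower for 1, 3 adjusted over the list alone (camera adjusted p = 8.39e-05, and 0.104 with an estimated correlation).

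Of the genes that rose with cisplatin in A549/cDDP, 398 of 611 also rose in A549, against 203.5 for independent lists (Fisher's exact test, odds ratio 3.94, p = 4.65e-60). Of those that fell, 617 of 782 also fell in A549, PLK1, CENPF and MCM6 among them, against 212.1 (Fisher's exact test, odds ratio 11.4, p = 1.19e-210). The genes that rose at least 2-fold in A549 had a median log2 change of 1.48 there and 0.12 in A549/cDDP, and those that fell at least 2-fold had -1.43 and -0.26. The count of 1393 became smaller when any library of this comparison was left out. That leaves 1 library in a group, so lost power and dependence on a particular library cannot be told apart.

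The response was then compared directly between the lines, as the difference of both cisplatin effects. All 29 damage-induced genes responded less in A549/cDDP, and CDKN1A, MDM2, FDXR and BTG2 showed some of the widest gaps. Most mitosis and replication genes on the lists fell less in the resistant line. Most of them were already lower there in solvent. SCAT7 and ELF3, which rose with the drug in A549, differed in the same sense as the damage-induced genes. The immediate early genes FOS and EGR1 differed the other way.

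The difference passed for 8088 genes, 3692 with a higher and 4396 with a lower response in A549/cDDP. Here too the majority turned, to 4322 higher and 3823 lower with median ratio scaling and 4126 and 3585 with quantile normalization. The difference was -3.96 for CDKN1A (limma adjusted p = 1.09e-14), -3.73 for MDM2 (limma adjusted p = 4.97e-11), -2.41 for ELF3-AS1 (limma adjusted p = 3.75e-06), -1.24 for ELF3 (limma adjusted p = 1.31e-07) and -0.33 for TOP1 on the log2 scale. For HNRNPK it was 0.23 (limma adjusted p = 0.00865, and 0.15 after quantile normalization), and YBX1 did not pass (limma adjusted p = 0.775). The genes with the lowest differences were SLC52A1 (-6.11), GRIN2C (-5.30), CEACAM1, NECTIN4 and SAA1, an acute phase protein gene. The highest were FOS (4.78), EGR1 (3.90), IL11, SLIT3 and SPOCK1. The damage-induced genes had a median of -2.37 with 29 of 29 lower (camera adjusted p = 3.27e-27, and 0.00128 with an estimated correlation), and the Fanconi anaemia and homologous recombination genes a median of 1 with 21 of 26 higher and 1 lower (camera adjusted p = 8.64e-10, and 0.0265 with an estimated correlation). Mitosis genes were higher for 23 of 25 and lower for 1 (camera adjusted p = 1.55e-16, and 0.164 with an estimated correlation), S phase genes for 23 of 25 and lower for 1 (camera adjusted p = 1.82e-17, and 0.0608 with an estimated correlation), and NF-kB and cytokine genes lower for 16 of 20 and higher for 1 (camera adjusted p = 2.09e-06, and 0.222 with an estimated correlation).

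In solvent, A549/cDDP, whose maintenance medium held cisplatin per the labels, differed from A549 at most genes. The resistant line held more of all 29 damage-induced genes, CDKN1A and FDXR among them, and less of every mitosis gene. It expressed the matrix enzymes PXDN, MMP2 and MMP9 and held very little of the airway mucins MUC5B and MUC5AC. The inflammatory genes IL6, CXCL1 and TNFAIP3 were higher. SCAT7 did not differ in solvent.

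The solvent libraries differed for 12075 genes, 7338 higher and 4737 lower in A549/cDDP. The median of all genes was 0.15 higher on the log2 scale, and 0.02 higher after median ratio scaling, so changes are best read against that shift; the share of calls that were higher was 60.8%, and 49.7% after median ratio scaling or 49.3% after quantile normalization. CDKN1A stood at 84.2 ± 0.123 FPKM in A549 and 577 ± 4.79 in A549/cDDP (log2 change 2.77, limma adjusted p = 1.26e-14), and MDM2 at 57.7 ± 1.25 and 291 ± 0.833 (log2 change 2.32, limma adjusted p = 2.45e-11). ELF3-AS1 stood at 3.12 ± 0.211 and 3.34 ± 0.635 (limma adjusted p = 0.696). ELF3 had a log2 change of -0.66, HNRNPK -0.47 and YBX1 -0.48, and all passed. TOP1 passed with 0.10, which became -0.05 after median ratio scaling and did not pass there.

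PXDN, a peroxidase of the basement membrane, stood at 2.14 ± 0.274 FPKM in A549 and 195 ± 2.74 in A549/cDDP. MMP2 and MMP9, gelatinases that cut matrix collagen, stood at 1.94 ± 0.0325 and 60.4 ± 0.996, and at 0.132 ± 0.0375 and 17.2 ± 1.53. GRIN2C, MAP2, PARP8, BST2 and ESM1 completed the largest rises. The largest falls were MTUS1 (80.9 ± 5.45 to 0.66 ± 0.113 FPKM), TM4SF4, TM4SF20, MUC5B (31.2 ± 1.67 to 0.0587 ± 0.019), MUC5AC, the peptide gene NTS, ST6GAL2 and FOS.

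Between the lines in solvent, damage-induced genes were higher for 29 of 29 with a median of 1.5 (camera adjusted p = 4e-13, and 0.018 with an estimated correlation). Mitosis genes were lower for 25 of 25 (camera adjusted p = 1.3e-14, and 0.178 with an estimated correlation) and S phase genes lower for 24 of 25 and higher for 1 (camera adjusted p = 3.54e-14, and 0.11 with an estimated correlation). Mesenchymal genes were higher for 16 of 21 and lower for 4 (camera adjusted p = 0.00255, and 0.178 with an estimated correlation), NF-kB and cytokine genes higher for 15 of 20 and lower for 3 (camera adjusted p = 0.00518, and 0.496 with an estimated correlation). YAP targets, including CCN1, CCN2 and ANKRD1, were lower for 9 of 13 and higher for 2 (camera adjusted p = 0.000839, and 0.0792 with an estimated correlation). CDKN2A, CDKN2B and MTAP lie in a chromosome 9 segment that A549 has lost, and none was tested because of low values: the highest FPKM in any of the 16 libraries was 0.399, 0.0157 and 0.24.

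With both lines in cisplatin, the order of the damage-induced genes turned around. CDKN1A, MDM2, GDF15 and BTG2 were now lower in A549/cDDP than in A549. Mesenchymal genes such as COL4A1 and COL5A1 and the cholesterol synthesis genes SQLE and LSS were higher in the resistant line. The epithelial cadherin CDH1 and keratin KRT19 were lower. SCAT7 was lower as well.

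In cisplatin the lines differed for 11437 genes, 6363 higher and 5074 lower in A549/cDDP, against 5570 and 5882 after median ratio scaling and 5536 and 5443 after quantile normalization. CDKN1A stood at 1620 ± 17.7 FPKM in A549 and 709 ± 1.64 in A549/cDDP (log2 change -1.19, limma adjusted p = 4.19e-12), and MDM2 at 811 ± 10.6 and 306 ± 10.1 (log2 change -1.40, limma adjusted p = 2.02e-09). ELF3-AS1 stood at 14.2 ± 1.36 and 2.41 ± 0.00294 (log2 change -2.33, limma adjusted p = 8.7e-08) and ELF3 at 99.9 ± 1.9 and 26.6 ± 2.03. TOP1 had a log2 change of -0.23, HNRNPK -0.25 and YBX1 -0.46, and all passed. The damage-induced genes were lower for 26 of 29 and higher for 1, with a median of -0.67 (camera adjusted p = 9.54e-11, and 0.0302 with an estimated correlation). Of 25 mitosis genes 10 were higher and 4 lower, median 0.14 (camera adjusted p = 0.656, and 0.964 with an estimated correlation). Of 25 S phase genes 17 were higher and 3 lower (camera adjusted p = 0.0461, and 0.752 with an estimated correlation). Of 26 Fanconi anaemia and homologous recombination genes 10 were higher and 5 lower, 4 adjusted over the list alone. Their camera adjusted p was 0.645, and 0.964 with an estimated correlation. Mesenchymal genes were higher for 18 of 21 and lower for 1, with a median of 1.49 (camera adjusted p = 1.12e-06, and 0.057 with an estimated correlation). Cholesterol synthesis genes were higher for 15 of 20 and lower for 4 (camera adjusted p = 0.00652, and 0.0824 with an estimated correlation). Epithelial genes were lower for 10 of 14 and higher for 2 (camera adjusted p = 0.00652, and 0.057 with an estimated correlation), and topoisomerase 1 and its repair lower for 9 of 12 and higher for 1 (camera adjusted p = 0.0242, and 0.0824 with an estimated correlation). Polyadenylated histone genes such as H2BC4 and H1-2 were higher for 7 of 9 and lower for 2 (camera adjusted p = 0.0298, and 0.403 with an estimated correlation). The genes of largest change included MAP2, SPOCK1, ESM1 and PKIA upward and SLC52A1, H19, SELENBP1 and VAMP8 downward.

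In A549/cDDP carrying the control gapmer, cisplatin gave a response of damage-induced genes again, small but nearly complete. FDXR, GDF15, BTG2, PPM1D and CDKN1A, all damage-induced genes, were among the genes that rose most. PLK1, CDC20 and KIF20A of the mitosis list fell. SLIT3, SPOCK1 and PIF1, which were among the largest falls in A549, fell here too. SCAT7 did not pass.

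Cisplatin changed 435 genes with the control gapmer, 288 higher and 147 lower, and 6 and 5 of them at least 2-fold. After median ratio scaling 190 were higher and 171 lower, and a fit of only the libraries compared left 270. CDKN1A went from 267 ± 2.2 to 448 ± 1.79 FPKM (log2 change 0.74, limma adjusted p = 3.12e-08), MDM2 from 168 ± 4.28 to 261 ± 17.7 (log2 change 0.63, limma adjusted p = 0.000289) and FDXR from 90.6 ± 1.75 to 182 ± 2.35. ELF3-AS1 stood at 3.06 ± 0.716 and 3.48 ± 0.351 (limma adjusted p = 0.724), and ELF3 had a log2 change of 0.28 (limma adjusted p = 0.0264, and 0.0632 after median ratio scaling). TOP1, HNRNPK and YBX1 did not pass (limma adjusted p = 0.631, 0.665 and 0.762). The damage-induced genes were higher for 27 of 29, 29 adjusted over the list alone, with a median of 0.47 (camera adjusted p = 1.6e-57, and 7.72e-05 with an estimated correlation). Mitosis genes were lower for 10 of 25, 23 adjusted over the list alone (camera adjusted p = 1.11e-25, and 0.137 with an estimated correlation). Mesenchymal genes such as TGFBI and FN1 were lower for 4 of 21, 11 adjusted over the list alone, and higher for 1, ACTA2 (camera adjusted p = 2.37e-10, and 0.0205 with an estimated correlation). Fanconi anaemia and homologous recombination genes, which passed as a list without transfection, had 1 of 26 higher and 0 lower by limma (camera adjusted p = 0.812, and 0.907 with an estimated correlation). Immediate early genes, which had also passed there, had 1 of 15 higher and 1 lower, 3 and 2 adjusted over the list alone (camera adjusted p = 0.832, and 0.907 with an estimated correlation). GPC6, IMMP2L, CPQ, SORCS2 and GMDS were the other large falls, and GRIN2C and INKA2 led the rises. Of these calls, 77 of the 288 rises and 82 of the 147 falls were also calls of the same direction in untransfected A549/cDDP, against 10.2 and 6.7 for independent lists (Fisher's exact test, p = 5.75e-46 and 3.83e-71). The log2 changes of both comparisons correlated across genes at a Pearson r of 0.105 and a Spearman rho of 0.134. In an overlap chosen after the results were seen, 273 of the rises and 142 of the falls were calls of the same direction in A549, where far more genes passed, against 95.9 and 39.9 (Fisher's exact test, p = 6.93e-111 and 7.97e-74). There the Pearson r was 0.375 and the Spearman rho 0.442. The count of 435 became 179, 140, 140 and 137 without control gapmer solvent replicate 1 or 2 or cisplatin replicate 1 or 2.

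The SCAT7 gapmer in solvent asked what the RNA does in resistant cells without the drug. Every mitosis gene and every S phase gene on the lists fell, KIF20A, BIRC5, AURKB and RRM2 among the strongest. The crosslink repair genes FANCI, FANCA, BRCA1 and RAD54L fell with them. CDKN1A, MDM2 and GDF15 rose against the control gapmer, as did NF-kB genes such as TNFAIP3 and CXCL8. CDKN1A and MDM2 were themselves lower with the control gapmer than without transfection. Many genes hardly expressed in control cells appeared, GRAMD2A and EFCAB8 among them.

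The SCAT7 gapmer changed 9605 genes in solvent, 5702 higher and 3903 lower, and 959 and 420 of them at least 2-fold. The split was 4991 and 4549 after median ratio scaling and turned to 4824 and 4839 after quantile normalization. CDKN1A went from 267 ± 2.2 to 625 ± 2.24 FPKM (log2 change 1.22, limma adjusted p = 3.08e-11) and MDM2 from 168 ± 4.28 to 447 ± 51.9 (log2 change 1.40, limma adjusted p = 6.03e-09). In untransfected A549/cDDP in solvent CDKN1A stood at 577 ± 4.79 and MDM2 at 291 ± 0.833. The SCAT7 gapmer libraries were not tested against the untransfected ones. YBX1 fell from 477 ± 15.4 to 342 ± 20.6. TOP1 rose from 47.4 ± 0.905 to 56.9 ± 1.29, and HNRNPK fell by 0.18 on the log2 scale. GRAMD2A went from 0.0117 ± 0.0165 to 20.8 ± 4.71 FPKM (limma adjusted p = 1.6e-10). EFCAB8 was at 0 in both control gapmer libraries and at 9.39 ± 1.58 with the SCAT7 gapmer, at least 1220-fold higher against 3 reads over the group. COL9A3, C8G, SCUBE2, FAM83E, RAPSN and SPON1-AS1 were the other largest rises. GRAMD2A, EFCAB8, SCUBE2 and SPON1-AS1 lie within 10 kb beyond the 3' end of an expressed gene. The largest falls were PIF1, KIF20A (42.1 ± 0.258 to 4.66 ± 0.632 FPKM), GTSE1, DLGAP5, TROAP, BIRC5 (180 ± 1.24 to 31.4 ± 5.3), AURKB and KIF18B.

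With the SCAT7 gapmer in solvent, mitosis genes were lower for 25 of 25 with a median of -2.26 (camera adjusted p = 3.66e-24, and 0.117 with an estimated correlation). The S phase genes were lower for 25 of 25 with a median of -1.53 (camera adjusted p = 9.26e-23, and 0.0437 with an estimated correlation). The Fanconi anaemia and homologous recombination genes were lower for 22 of 26, 23 adjusted over the list alone, and higher for 1 (camera adjusted p = 9.25e-13, and 0.0143 with an estimated correlation). The damage-induced genes were higher for 26 of 29 with a median of 0.72 (camera adjusted p = 1.57e-11, and 0.0143 with an estimated correlation). NF-kB and cytokine genes were higher for 18 of 20 and lower for 1 (camera adjusted p = 7.14e-06, and 0.28 with an estimated correlation), and immediate early genes higher for 11 of 15 and lower for 2, ATF3 foremost (camera adjusted p = 0.0101, and 0.339 with an estimated correlation). Cholesterol synthesis genes were higher for 12 of 20 and lower for 1 (camera adjusted p = 0.0141, and 0.13 with an estimated correlation). Mitochondrial transcripts, MT-ND6 and MT-ATP6 among them, were lower for 9 of 13 (camera adjusted p = 0.00212, and 0.386 with an estimated correlation). One gapmer against SCAT7 was used, so effects of SCAT7 loss and of the oligonucleotide on other RNAs were not separated.

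Genes that fell with the SCAT7 gapmer were also enriched among those that fell with cisplatin. Of the 782 genes lower with cisplatin in untransfected A549/cDDP, PLK1, CENPF and FANCI among them, 490 were lower with the gapmer, against 177.5 for independent lists (Fisher's exact test, odds ratio 6.39, p = 1.62e-133). Of the 611 higher genes, CDKN1A and RRM2B included, 390 were higher with the gapmer, against 202.6 (Fisher's exact test, odds ratio 3.75, p = 5.17e-56). The log2 changes of both comparisons correlated across genes at a Pearson r of 0.235 and a Spearman rho of 0.257. Genes that change together can give such an excess without a shared cause. Transfection in solvent and cisplatin in A549 overlapped in opposite directions with odds ratios of 6.53 and 5.08. The overlap alone therefore cannot show that the gapmer acts like the drug.

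**Figure D2:**
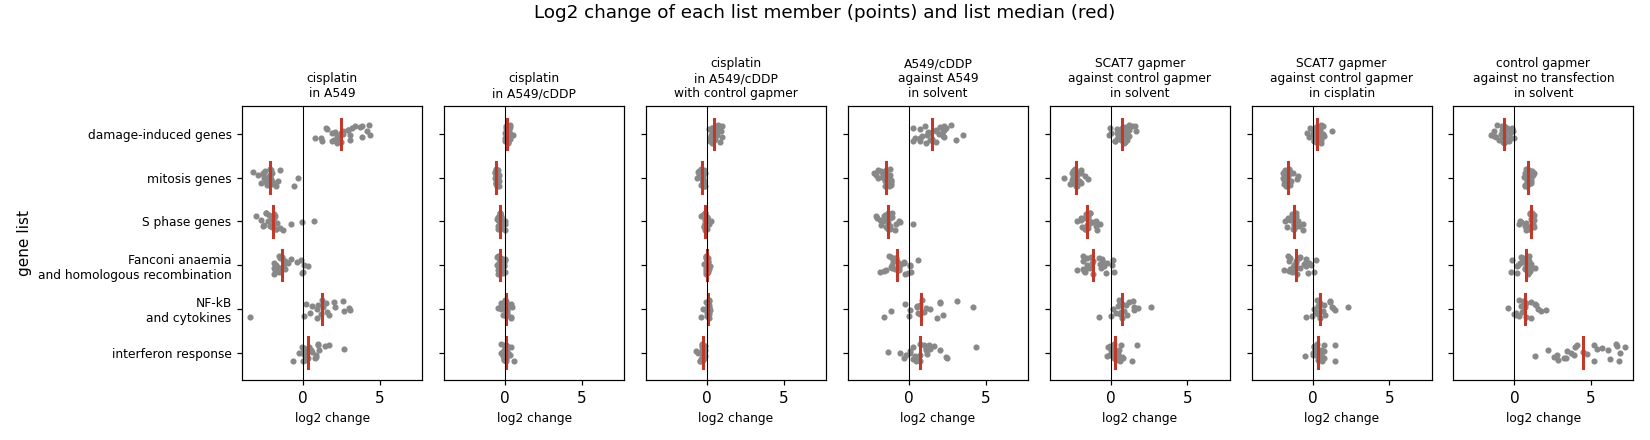
Log2 change of each member (grey points) of 6 gene lists on the vertical axis in 7 comparisons (panels), with the list median as a red line; the horizontal axis is the log2 change. Mitosis genes have a median of -2.19 with cisplatin in A549 and -2.26 with the SCAT7 gapmer in solvent, and damage-induced genes have 2.49 and 0.72.

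In cisplatin, the SCAT7 gapmer left much the same mark. Mitosis genes such as PLK1 and ANLN, S phase genes such as RRM2 and MCM6 and the repair genes FANCI and BRCA1 were lower than with the control gapmer. CDKN1A and RRM2B of the damage-induced genes were higher. The inflammatory genes CXCL8 and IL1A and the weakly expressed genes GRAMD2A and EFCAB8 rose again.

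The gapmer changed 8545 genes in cisplatin, 4916 higher and 3629 lower, or 4420 and 3950 after median ratio scaling. Of the rises 4369 and of the falls 3053 were also calls in solvent, GRAMD2A and PIF1 for example, and the log2 changes correlated across genes at a Pearson r of 0.883 and a Spearman rho of 0.845, with a slope of 0.755. CDKN1A went from 448 ± 1.79 to 663 ± 3.16 FPKM (log2 change 0.57, limma adjusted p = 1.44e-08) and MDM2 from 261 ± 17.7 to 425 ± 10.7. In untransfected A549/cDDP in cisplatin CDKN1A stood at 709 ± 1.64 and MDM2 at 306 ± 10.1. ELF3 rose by 0.20 on the log2 scale and YBX1 fell by 0.31, while TOP1 and HNRNPK did not pass (limma adjusted p = 0.0627 and 0.547). Mitosis genes were lower for 25 of 25 with a median of -1.59 (camera adjusted p = 1.52e-23, and 0.0928 with an estimated correlation), S phase genes for 25 of 25 (camera adjusted p = 1.76e-23, and 0.06 with an estimated correlation). Fanconi anaemia and homologous recombination genes were lower for 22 of 26 and higher for 1, 23 and 2 adjusted over the list alone (camera adjusted p = 5.72e-14, and 0.0159 with an estimated correlation). The damage-induced genes were higher for 21 of 29, 22 adjusted over the list alone, and lower for 3 (camera adjusted p = 5.61e-05, and 0.0742 with an estimated correlation). Polyadenylated histone genes, H1-2 and H2AC6 among them, were higher for 7 of 9 and lower for 1 (camera adjusted p = 0.000672, and 0.148 with an estimated correlation). HCLS1 and PYGM joined the largest rises, and SNORD19, TK1, NEK2 and MYBL2 the largest falls.

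Whether the drug changes the effect of the gapmer was tested as a difference of effects. In cisplatin the gapmer raised the damage-induced genes CDKN1A, MDM2 and GDF15 by less than in solvent, while FDXR had a lower mean with it in cisplatin and a higher one in solvent. It lowered the mitosis genes KIF20A, PLK1 and DLGAP5 by less. SCAT7 itself did not pass, but its mean went from 3.06 to 0.716 FPKM in solvent and from 3.48 to 1.93 in cisplatin. A shallower knockdown in cisplatin and an effect of the drug therefore cannot be told apart.

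The difference passed for 160 genes, 84 higher and 76 lower, but for only 10 in a fit of the libraries compared alone. It was -0.66 for CDKN1A (limma adjusted p = 1.38e-05), -0.70 for MDM2 (limma adjusted p = 0.00574), -0.93 for GDF15 (limma adjusted p = 0.00015) and -0.70 for FDXR (limma adjusted p = 1.38e-05). It was 1.14 for KIF20A, 0.95 for PIF1 and 0.79 for PLK1. For ELF3-AS1 it was 0.83 (limma adjusted p = 0.14), and ELF3, TOP1, HNRNPK and YBX1 did not pass (limma adjusted p = 0.282, 0.268, 0.332 and 0.197). The damage-induced genes were lower for 17 of 29, 25 adjusted over the list alone, with a median of -0.38 (camera adjusted p = 7.16e-36, and 0.000478 with an estimated correlation). Mitosis genes were higher for 18 of 25, 25 adjusted over the list alone (camera adjusted p = 5.49e-39, and 0.0627 with an estimated correlation), and S phase genes for 7 of 25, 18 adjusted over the list alone (camera adjusted p = 4.2e-20, and 0.0627 with an estimated correlation). The count of 160 became 45 or 52 without control gapmer solvent replicate 1 or 2, 70 or 48 without control gapmer cisplatin replicate 1 or 2, 55 without SCAT7 gapmer solvent replicate 1 and 462 without SCAT7 gapmer cisplatin replicate 2.

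Transfection itself was read from the control gapmer against untransfected A549/cDDP, both in solvent. All 25 interferon response genes rose, as they do when cells sense foreign nucleic acid, IFI27, OAS2, RSAD2 and IFI6 foremost. Mitosis, S phase and crosslink repair genes were higher after transfection. The damage-induced genes CDKN1A and FDXR and the cholesterol synthesis genes SQLE and LSS were lower. SCAT7 did not pass.

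The control gapmer libraries differed from the untransfected ones at 6828 genes, 3562 higher and 3266 lower, which turned to 3179 and 3759 after quantile normalization; they were also collected later after seeding. IFI27 went from 1.01 ± 0.259 to 225 ± 40.3 FPKM (log2 change 7.23, limma adjusted p = 6.48e-09) and IFI6 from 14.2 ± 0.175 to 1530 ± 155, with MX1, XAF1 and IFI44L close behind. CDKN1A fell from 577 ± 4.79 to 267 ± 2.2 (limma adjusted p = 1.57e-10) and MDM2 from 291 ± 0.833 to 168 ± 4.28 (limma adjusted p = 2.06e-06). HNRNPK rose by 0.14 on the log2 scale, and ELF3-AS1, ELF3, TOP1 and YBX1 did not pass (limma adjusted p = 0.633, 0.639, 0.54 and 0.122). The largest falls included GRIN2C, ACO1 and AJUBA-DT. Interferon response genes had a median of 4.47 (camera adjusted p = 4.06e-28, and 0.0661 with an estimated correlation). S phase genes were higher for 25 of 25 with a median of 1.07 (camera adjusted p = 1.75e-22, and 0.0296 with an estimated correlation), mitosis genes for 25 of 25 (camera adjusted p = 1.32e-18, and 0.118 with an estimated correlation). Fanconi anaemia and homologous recombination genes were higher for 23 of 26 and lower for 1 (camera adjusted p = 2.14e-12, and 0.0084 with an estimated correlation). The damage-induced genes were lower for 27 of 29 with a median of -0.70 (camera adjusted p = 9.26e-21, and 0.00262 with an estimated correlation), and cholesterol synthesis genes for 16 of 20 (camera adjusted p = 3.87e-12, and 0.00262 with an estimated correlation). Epithelial genes were higher for 9 of 14 and lower for 1 (camera adjusted p = 0.00108, and 0.0296 with an estimated correlation).

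Platinum transport and nucleotide excision repair genes showed no shift in a shared direction as lists, though many members differed between the lines. In solvent, where 70.2% of all genes passed, platinum transport genes were higher in A549/cDDP for 9 of 17 and lower for 7. Nucleotide excision repair genes were higher for 11 of 24 and lower for 8, 12 and 10 adjusted over the list alone. In cisplatin, where 66.5% of all genes passed, the counts were 9 and 5 for transport and 6 and 12 for excision repair. As lists, platinum transport, nucleotide excision repair, metallothionein, and hypoxia and glycolysis genes passed in none of the 10 comparisons. Their lowest camera adjusted p-values were 0.248, 0.167, 0.239 and 0.0786. Lung epithelium markers, with 7 of 17 members measured, and other-lineage markers, with 6 of 27, did not pass either, at lowest camera adjusted p-values of 0.439 and 0.525. The list of the deleted locus on chromosome 9 had no tested member. The other lists passed in 2 to 10 comparisons each with the preset correlation.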

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

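In this part, the test of evenly spread reads and the tests of a missing drug, of the level of the damage-induced genes in cisplatin and of drug left over from the culture were chosen after the results were seen.

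The response to cisplatin differed between A549/cDDP and A549 for 8088 genes by a test of the difference itself. The damage-induced genes differed by a median of -2.369 on the log2 scale and the Fanconi anaemia and homologous recombination genes by a median of 1. Single genes that differed were CDKN1A (-3.96), MDM2 (-3.73), ELF3-AS1 (-2.41), ELF3 (-1.24), TOP1 (-0.33) and HNRNPK (0.23). In A549, CDKN1A, MDM2, ELF3-AS1 and ELF3 were higher in 2 of 2 cisplatin libraries than in both solvent libraries. The HNRNPK call is the weakest of these and ends under quantile normalization.

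The effect of the SCAT7 gapmer differed between cisplatin and solvent for 160 genes, also by a test of the difference. The damage-induced genes differed by a median of -0.383, CDKN1A by -0.66 and MDM2 by -0.70. The mean fall of ELF3-AS1 was also smaller in cisplatin, so depth of knockdown and drug cannot be told apart. CDKN1A and MDM2 were higher with the SCAT7 gapmer than with the control gapmer in 2 of 2 libraries under both treatments. This count is small: it was 10 in a fit of only the libraries compared, and it moves with single libraries, from 45 without control gapmer solvent replicate 1 to 462 without SCAT7 gapmer cisplatin replicate 2.

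Olfactory receptor genes, which no comparison covered, had a higher summed FPKM in the SCAT7 gapmer libraries. The sums over 376 such genes were 3.20 and 2.86 in solvent and 2.87 and 3.77 in cisplatin for replicates 1 and 2. The other 12 libraries lay between 0.502 and 1.36.

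The rise of weakly expressed genes with the SCAT7 gapmer was weighed first. In solvent, 494 genes under 1 FPKM with the control gapmer rose at least 2-fold, by a median of 2.07 FPKM. Reads spread evenly over the genome, as from DNA, would raise all weakly expressed genes alike, but of 8913 such genes outside expressed genes, risen or not, only 9.12% rose by at least 0.5 FPKM, and their median rise was 0.0258 FPKM. Scaling by the library total was argued against because 93.7% of the 494 genes (463) were still called and at least 2-fold higher after median ratio scaling.

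Transcription running on past the end of an expressed neighbour, a failure to stop at the 3' end, predicts a rise beyond the neighbour's 3' end and not beyond its 5' end. Of weakly expressed genes, called or not, within 10 kb beyond an expressed gene's 3' end, 210 of 1166 (18.01%) rose at least 2-fold, against 26 of 963 (2.70%) beyond a 5' end and 215 of 6482 (3.32%) near neither. The ratio was 6.67 (Fisher's exact test, p = 6.26e-33), and 7.26 in cisplatin. Genes on the neighbour's strand rose in 29.55% and those on the opposite strand in 5.09%, and GRAMD2A beyond PKM, SCUBE2 beyond DENND5A, EFCAB8 beyond MAPRE1 and PYGM beyond SF1 are examples. Read-through may therefore explain part of this rise, while of the 494 pattern genes 111 near neither end, 15 beyond a 5' end only, 68 that overlap an expressed gene and 136 of types or chromosomes outside this test stay unexplained, and whether loss of SCAT7 or another effect of this gapmer leads to it was not tested.

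The smaller cisplatin response of A549/cDDP was weighed next. Falls shared with A549 were 2.91 times as many as independent lists would share, where a missing drug was taken to give no excess. That ratio cannot decide whether drug was missing from the A549/cDDP cisplatin libraries. Genes that change together can exceed such a count in a contrast between solvent libraries too. Of genes higher with the control gapmer than without transfection in solvent, 2131 were lower with cisplatin in A549, against 966. Damage-induced genes already at their cisplatin level in solvent would reach the same level in cisplatin if both lines share a ceiling. Their median difference, A549/cDDP minus A549, was -0.672, with 26 of 29 lower, so most did not reach the level of A549. Whether A549/cDDP has a lower ceiling of its own cannot be decided this way. Per the labels, A549/cDDP was kept in cisplatin, and drug left over in its solvent libraries could raise the starting level of CDKN1A and MDM2: damage-induced genes were lower in the control gapmer libraries, collected later after seeding, with a median difference of -0.70. Transfection and time differ together there and cannot be told apart. Gene span bears on a missing drug. The log2 change had a Spearman correlation with span of -0.249 in A549/cDDP, -0.277 with the control gapmer and -0.203 in A549. Contrasts of solvent libraries gave 0.039 between the lines, 0.023 for transfection and 0.096 for the SCAT7 gapmer. A missing drug would leave no fall of long genes shared with A549, so these values argue against it in both A549/cDDP contrasts. A raised starting level, left-over drug, less drug or damage in the resistant cells and an altered response all stay open.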

How the results depend on the processing

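The voom fit, the fits of the untransfected or transfected set alone and the fits without the SCAT7 gapmer libraries were chosen after the data were seen. The counts of genes for cisplatin in A549, the difference between the lines' responses, both contrasts between the lines, the SCAT7 gapmer in solvent and in cisplatin, and transfection stayed within 1.5 times of their values under every alternative except the 2-fold requirement. No other splits of the samples were counted, since groups hold 2 libraries.

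Requiring a change of at least 2-fold left 2115 genes for cisplatin in A549, 17 in A549/cDDP and 1870 for their difference, 3051 and 2535 between the lines in solvent and cisplatin, 11 for cisplatin with the control gapmer, 1379 and 999 for the SCAT7 gapmer in solvent and cisplatin, 10 for its difference and 474 for transfection; the rule itself sets these lower counts. An adjusted p under 0.01 left 560 genes for cisplatin in A549/cDDP, 169 with the control gapmer and 43 for the gapmer difference, again by construction. Fitting only the libraries compared, with fewer degrees of freedom, gave 417, 270 and 10 for the same contrasts. The transfected set alone gave 146 and 10 for the last 2 of them. Voom gave 693 genes for cisplatin with the control gapmer and 247 for the gapmer difference, and no filter gave 262 for the latter; the cause was not tested.

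Leaving out 1 library, with the lone one assumed to vary like the other groups, gave 9167 to 9287 genes for cisplatin in A549, 509 to 1049 in A549/cDDP, 7217 to 7650 for their difference, 10962 to 11072 and 10245 to 10612 between the lines in solvent and cisplatin, 137 to 179 for cisplatin with the control gapmer, 7898 to 8919 and 6650 to 8464 for the SCAT7 gapmer in solvent and cisplatin, 45 to 462 for its difference and 5103 to 5268 for transfection. The count for A549/cDDP was 597, 509 and 531 without solvent replicate 1, solvent replicate 2 and cisplatin replicate 2. For the control gapmer it was 179, 140, 140 and 137 without solvent 1, solvent 2, cisplatin 1 and cisplatin 2. For the gapmer difference it was 45, 52, 70 and 48 without the same control libraries in that order, 55 without SCAT7 gapmer solvent 1 and 462 without SCAT7 gapmer cisplatin 2.

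Scaling moved the split of calls between the lines in solvent from 60.8% higher to 49.7% with median ratio scaling (5982 higher, 6050 lower) and 49.3% with quantile normalization, and for cisplatin with the control gapmer from 66.2% to 52.6% with median ratio scaling. The majority of calls turned as well for cisplatin in A549 (5729 higher and 4664 lower, against 5062 and 5328 with median ratio scaling), the difference between the lines' responses (3692 and 4396, against 4322 and 3823), and both lines in cisplatin (6363 and 5074, against 5570 and 5882). With quantile normalization it turned to 4762 and 5224 for the first and 4126 and 3585 for the second of these, 4824 and 4839 for the SCAT7 gapmer in solvent and 3179 and 3759 for transfection. TOP1 between the lines in solvent reversed to -0.052 with median ratio scaling; that scaling shifts all genes of this contrast down. Of the other results for named genes, each a gene in 1 comparison, 571 kept their call there and 1 gained and 3 lost it. Of the list tests, 77 lost their call with an estimated correlation, and quantile normalization ended 6 and added 10.

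Same-numbered replicates deviated together little (correlations of deviations of -0.073 to 0.071 between groups compared directly, 0.113 between both SCAT7 gapmer groups and -0.187 to 0.119 over all pairs), so the numbers were not taken to pair the libraries. With a replicate block the counts were 10359, 1286, 8031, 12063, 11391, 381, 9556, 8499, 124 and 6713 in the order of the 2-fold counts above; no list test changed its call and 9 such results for named genes lost theirs.

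Depth limits ELF3-AS1 with the SCAT7 gapmer in solvent to 104 and 156 reads, and genes at 0 to the floor of 3 reads over a group.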

Other observations

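In this part, the counts of lower and higher genes by gene span, the values of 3' end factors and the comparison of transfection with cisplatin in A549 were chosen after the results were seen; the correlations with gene span were not.

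Long genes were lower with cisplatin in A549 more often than short ones: of the 943 genes over 200 kb, 601 were lower and 152 higher by limma, and of the 2451 under 10 kb, 597 and 948. Across 12966 protein-coding genes, which are not independent replicates, the log2 change had a Spearman correlation of -0.203 with the span of the gene. Genes under 10 kb had a median log2 change of 0.10 and those over 200 kb one of -0.42, and EXOC4 (814 kb), SLIT3 (639 kb), CDH4 (688 kb), SPOCK1 (623 kb) and NTRK3 (397 kb) were among the largest falls. Transcript length was argued against by a median correlation of -0.201 within 10 bins of exon length, and expression level by -0.183 within 10 bins of mean expression. A candidate explanation is that adducts stop polymerases on long genes in both lines: the correlation was -0.249 in A549/cDDP, the weaker of both cisplatin contrasts of that line, and -0.277 with the control gapmer, where GPC6 (1181 kb) fell most, against 0.039 between the lines in solvent and 0.023 for transfection. The fall was smaller in the resistant line, though. Genes over 200 kb had a median log2 change of -0.13 in A549/cDDP and -0.07 with the control gapmer. The difference between the lines' responses correlated with span at 0.15, both lines in cisplatin at 0.166 and the SCAT7 gapmer in solvent at 0.096.

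Factors that end transcription or cleave its 3' end were looked up because of the read-through pattern. Of 31 measured, 17 were lower and 6 higher with the SCAT7 gapmer in solvent by limma, with a median log2 change of -0.16, and 13 were lower and 5 higher in cisplatin, with -0.09. In solvent CPSF3 had a log2 change of -0.59, NUDT21 -0.51 and TTF2 -0.78, and PCF11 had 1.15.

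Genes that differed between the control gapmer and no transfection mostly changed in the opposite direction with cisplatin in A549. The control gapmer libraries were also collected later after seeding, so transfection and time cannot be told apart here. Of 3562 genes higher with the control gapmer than without transfection, 2131 were lower with cisplatin in A549, against 966 for independent lists (Fisher's exact test, odds ratio 6.53). Of 3266 lower genes, 2096 were higher, against 1088 (odds ratio 5.08). Another 554 genes were higher in both and 437 lower in both, against 1186.6 and 885.7. The log2 changes correlated across genes at a Pearson r of -0.352 and a Spearman rho of -0.424.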
